A study of Homo sapiens with 6 samples.

How the data were processed

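RNA of PC-3 cells, a human prostate cancer line, was measured by RNA sequencing in 6 libraries, 3 from cells given trans-Gnetin H (TGH) and 3 from cells given the solvent dimethyl sulfoxide (DMSO). Per the labels' protocols, total RNA of a set minimum integrity was depleted of ribosomal RNA and made into libraries with a kit that keeps the strand. The values used were deposited by the authors as log2(TPM + 1), where TPM is a unit of transcript abundance that scales reads by transcript length and by library total. The deposited table has 1 row per gene symbol, 18780 in all, and 1 column per library. The offset of 1 was read from the values, whose smallest is exactly 0. The genome build was hg19, per the submitters' processing notes. The aligner, the quantifier, the gene annotation and any filter on genes are not given in the sources used here. The listed TPM of a library sum to between 502380 and 518870, which is 50.2% to 51.9% of what a complete column of this unit sums to, and what makes up the remainder is not known. No mitochondrially encoded gene has a value in this table, and all coordinates are left out because the table gives symbols alone.

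TPM keeps no read total, so the depth of a library is not known. The steps between low TPM values of 1 gene in 2 libraries carry a trace of relative depth, and were searched for among values under 0.1 TPM with a tolerance of 0.015 on the log2 scale. Set to 1 for DMSO replicate 3, the relative depth came out as 0.188 for DMSO replicate 1, 0.171 for DMSO replicate 2, and 0.771, 0.693 and 0.821 for TGH replicates 1 to 3. These figures hold only to about a factor of 2. How ratios of read numbers were weighed was changed after the real values and the zeros per library had been seen, and the settings of the simulation were changed together with it. All 3 weightings tried were therefore run under both simulation settings, on 18780 genes at 5 known depths each. The weighting used here erred by at most 0.83% under one simulation setting and by 98.3% under the other, and no weighting stayed under 5% in both. For DMSO replicate 2 a second weighting gave 0.345 instead of 0.171, while the values of the other libraries differed by little or not at all. Under each weighting DMSO replicates 1 and 2 were the shallowest libraries. No test below computes with these figures. They name the control libraries that are left out in one alternative, and whose low depth is weighed as an explanation under the other observations.

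Before the data were examined, the test, the gene lists, the rule for named genes and all alternatives except those named below were fixed. Genes with a mean of at least 1 TPM over the 6 libraries were kept, 12018 in all. The deposited log2 values were compared between TGH and DMSO with limma 3.58.1 in R 4.3.3 (linear model, moderated variances with a trend on expression), two-sided, with Benjamini-Hochberg adjustment over the genes kept and a call at an adjusted p under 0.05. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. Figures were drawn with matplotlib 3.10.9.

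The fixed lists were 35 gene lists and 7 lists of cell type markers and structural RNAs. Each list with at least 3 kept members was tested against all other genes with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 36 lists. Camera with an estimated correlation and camera on ranks were run beside it. The genes named are the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, SLC2A1, SLC2A3, HK2, LDHA, TXNIP and ARRDC4 whatever their result, and up to 4 members of each list with the smallest p. A gene named outside this rule is said to be so, and the values of some genes under the rule are not reported here.

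On simulated tables with the spread of the real libraries, 10 tables of 12018 genes with 200 changed genes each, the limma step called 42.0% of genes changed by 0.25 on the log2 scale, 77.9% of those changed by 0.5 and 95.3% of those changed by 1, and 4.28% of its calls were false. A list shifted by 0.3 was called in 10 of 10 tables, and 0 of 390 unshifted lists were called by camera. Only 200 of 12018 genes were changed in each table, while 55.2% of the genes kept were called in the data. The p needed for a call depends on that share, so the percentages of changed genes called do not carry over to the real comparison. The simulated genes varied independently of each other, so this does not show how often camera calls unshifted lists of correlated genes.

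The alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter or a mean of at least 5 TPM, median scaling, quantile normalization, rescaling without small RNAs, variances without trend or robust, the replicate number as a block, and leaving out each library in turn. Added after the data had been seen were DMSO replicate 3 as the only control, a fit whose spread comes from the TGH libraries alone, and exact zeros taken as missing in genes whose median is above 3 on the log2 scale. The labels do not say that the replicates are separate cultures, so the p-values measure the spread between these samples, which may be technical.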

Results

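The data are 6 RNA sequencing libraries of PC-3, a human prostate cancer cell line grown in culture. Cells received TGH, a trimer of the plant polyphenol resveratrol, at 2.5 µM for 24 h (n = 3), or the solvent DMSO as the control (n = 3). By its title the study addresses glucose deprivation by a compound in advanced prostate cancer, so transcripts of glucose uptake, of glycolysis and of the transcriptional response to glucose were the primary lists. The number of genes listed at exactly 0 was 3074, 3185 and 1530 in DMSO replicates 1 to 3, and 1469, 1498 and 1342 in TGH replicates 1 to 3. DMSO replicates 1 and 2 were shallower than the other libraries, by an estimate that is good to about a factor of 2.

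Cells given TGH had much less TXNIP mRNA, more mRNA of endoplasmic reticulum (ER) chaperones and of amino acid response genes, and less mRNA of glycolytic enzymes and of cell division genes. TXNIP is an arrestin-like protein that restrains glucose uptake and is transcribed in response to glucose. It went from 105 ± 2.37 TPM in DMSO to 5.76 ± 0.276 TPM with TGH (SD, n = 3 each). On the log2(TPM + 1) scale it was 15.7-fold lower (limma with Benjamini-Hochberg adjustment, adjusted p = 3.4e-08). The offset of 1 makes this smaller than the fold between the TPM values, and the folds below are on the same scale. HSPA5, the main chaperone of the ER lumen, went from 203 ± 2.69 to 642 ± 5.74 TPM, 3.15-fold higher (adjusted p = 3.4e-08). LDHA, which makes lactate from pyruvate, went from 991 ± 12.5 to 580 ± 2.42 TPM, 1.71-fold lower (adjusted p = 5.8e-07). PLK1, a kinase of mitosis, went from 71.5 ± 1 to 29.6 ± 0.368 TPM (adjusted p = 6.3e-07).

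Of 12018 genes kept, 3479 were higher with TGH, 3156 were lower and 5383 were not called. Most of these differences were small: 80.8% of the called genes differed by less than 0.5 on the log2 scale. At least a 2-fold difference was found for 113 higher and 31 lower genes, numbers that depend on the pseudocount, with 249 higher genes at a pseudocount of 0.1 and 44 higher and 9 lower genes at 5. The groups did not overlap in 7739 genes (64.4%, where chance gives 10%). With DMSO replicate 3 as the only control 3071 genes were higher and 2757 lower. In that comparison the lone control is assumed to vary like the TGH libraries, which alone supply the spread, and all its libraries are also in the full comparison.

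**Figure D1:**
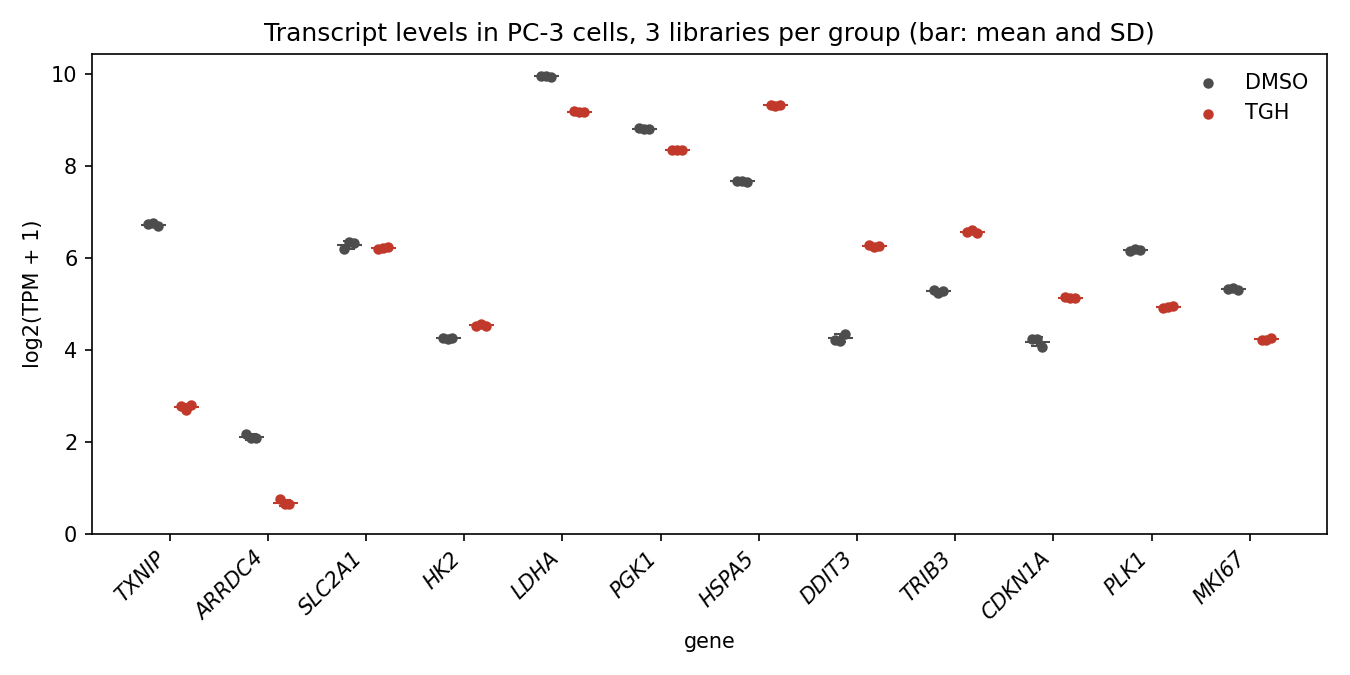
Transcript levels of 12 named genes, as log2(TPM + 1) on the vertical axis, with 1 point per library, DMSO in grey and TGH in red, and bars for the mean and SD of 3 libraries. TXNIP lies at 2.76 on average with TGH against 6.73 with DMSO, while the SLC2A1 points of the groups lie close together.

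Among protein-coding genes the largest rises were those of TM4SF19, a membrane protein, by 2.08 on the log2 scale (SE 0.171), HERPUD1, which serves ER-associated degradation, by 2.04 (SE 0.055), DDIT3, the stress transcription factor CHOP, by 2.01 (SE 0.044), and CRELD1, an ER protein, by 1.92 (SE 0.067). The largest falls, after TXNIP at -3.97, were DHRS2, a short-chain dehydrogenase, at -1.76, ARRDC4, a relative of TXNIP, at -1.43, KIF20A, a kinesin of cell division, at -1.41, and DMBT1, a secreted scavenger receptor protein, at -1.36. HIST1H1E, a linker histone, and GCSHP3, a pseudogene of a glycine cleavage protein, both had -1.33. Reads of either can be shared with near-identical copies, so these values are uncertain. The adjusted p of these genes lay at or below 0.0016.

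Small RNAs were among the largest rises and falls, and their values are uncertain. MIR941-2, a microRNA, and SNORA60, SNORA78 and RNU11, which guide RNA modification or serve splicing, were listed at 0 in all 3 DMSO libraries. With TGH the log2 values of replicates 1 to 3 were 4.62, 4.79 and 4.55 for MIR941-2, 4.20, 3.81 and 4.84 for SNORA60, 3.48, 3.64 and 4.91 for SNORA78, and 4.28, 4.84 and 2.77 for RNU11. MIR3652 rose by 3.41 and SNORA84 by 4.03, but SNORA84 was not called against DMSO replicate 3 alone (2.25, adjusted p = 0.0506). SNORA34 had -2.50 (adjusted p = 0.0242) and BCYRN1, a small cytoplasmic RNA, -1.31 (adjusted p = 0.0269). Both calls were lost under several settings, SNORA34 with 0.245 against DMSO replicate 3 alone.

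Transcripts for glucose uptake did not move as a group. Of 6 members measured, 2 were higher, 1 was lower and 3 were not called, with the same counts adjusted over the list alone (camera adjusted p = 0.787). The list's median was -0.01, while its mean was 0.16 and the test's direction was up. SLC2A1, the glucose transporter GLUT1, was at 77.1 ± 4.61 TPM in DMSO and 73.5 ± 0.954 TPM with TGH, a difference of -0.07 (SE 0.044, adjusted p = 0.246). It was called lower without DMSO replicate 1 (-0.11, adjusted p = 0.0095). Against DMSO replicate 3 alone, where the wider spread of SLC2A1 in DMSO does not enter, it had -0.10 (adjusted p = 0.0449). SLC2A3, the transporter GLUT3, was listed at 0 in 4 libraries and was at most 0.0172 TPM. SLC2A10, another member of the transporter family, rose by 0.87 and HK2, a hexokinase, by 0.29, while HK1 fell by 0.14.

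Glycolytic transcripts fell. Of 20 measured, 17 were lower, 1 was higher and 2 were not called, with the same counts adjusted over the list alone, and the median was -0.36 (camera adjusted p = 1.6e-07, and adjusted p = 0.0276 with an estimated correlation). LDHA fell by 0.77, PGAM1 by 0.54, ENO1 by 0.48 and PGK1 by 0.46. PKM, which makes pyruvate and was named after its values were seen, was listed at 0 in TGH replicate 2 and at 9.16 and 9.19 on the log2 scale in the other TGH libraries, against 9.73, 9.71 and 9.73 in DMSO. Without that library PKM was called at -0.55, and the mean of the list went from -0.48 to -0.33.

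The glucose-responsive list, genes read by the glucose sensors MondoA and ChREBP, had 4 lower, 1 higher and 2 uncalled members of 7, and 4 lower and 2 higher adjusted over the list alone. As a group it was not called (camera adjusted p = 0.0795, median -0.25, mean -0.85). TXNIP and ARRDC4 fell, and so did KLF10, a transcriptional repressor, by 0.80, while ARRDC3 rose by 0.16, a call lost under 5 settings, such as without DMSO replicate 3 (adjusted p = 0.0522). Its adjusted p was 0.325 with an estimated correlation and 0.182 on ranks. Without the filter on low values the list was called (adjusted p = 0.0454), with a smaller mean of -0.66. In the pentose phosphate pathway, which makes NADPH and ribose, 7 of 9 transcripts were lower and 1 was higher (8 lower and 1 higher adjusted over the list alone). TKT fell by 0.47 and PRPS1 by 0.41 (camera adjusted p = 0.0055, and adjusted p = 0.120 with an estimated correlation).

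ER chaperones and unfolded protein response genes rose without exception. All 18 measured were higher, also adjusted over the list alone, with a median of 1.28 (camera adjusted p = 7.3e-15, and adjusted p = 0.0241 with an estimated correlation). MANF, a secreted ER stress protein, rose by 1.87 (SE 0.019), PDIA4, a disulfide isomerase, by 1.78 (SE 0.018), HSPA5 by 1.66 (SE 0.017) and HSP90B1, the ER form of HSP90, by 1.51 (SE 0.020). In the amino acid response list, targets of the transcription factor ATF4, 22 of 24 were higher, 1 was lower and 1 was not called, the same adjusted over the list alone. Its median was 0.84 (camera adjusted p = 4.8e-11, and adjusted p = 0.0241 with an estimated correlation). SLC3A2, a subunit of amino acid transporters, rose by 1.37, TRIB3, a pseudokinase, by 1.29 and STC2, a secreted glycoprotein, by 1.12.

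**Figure D2:**
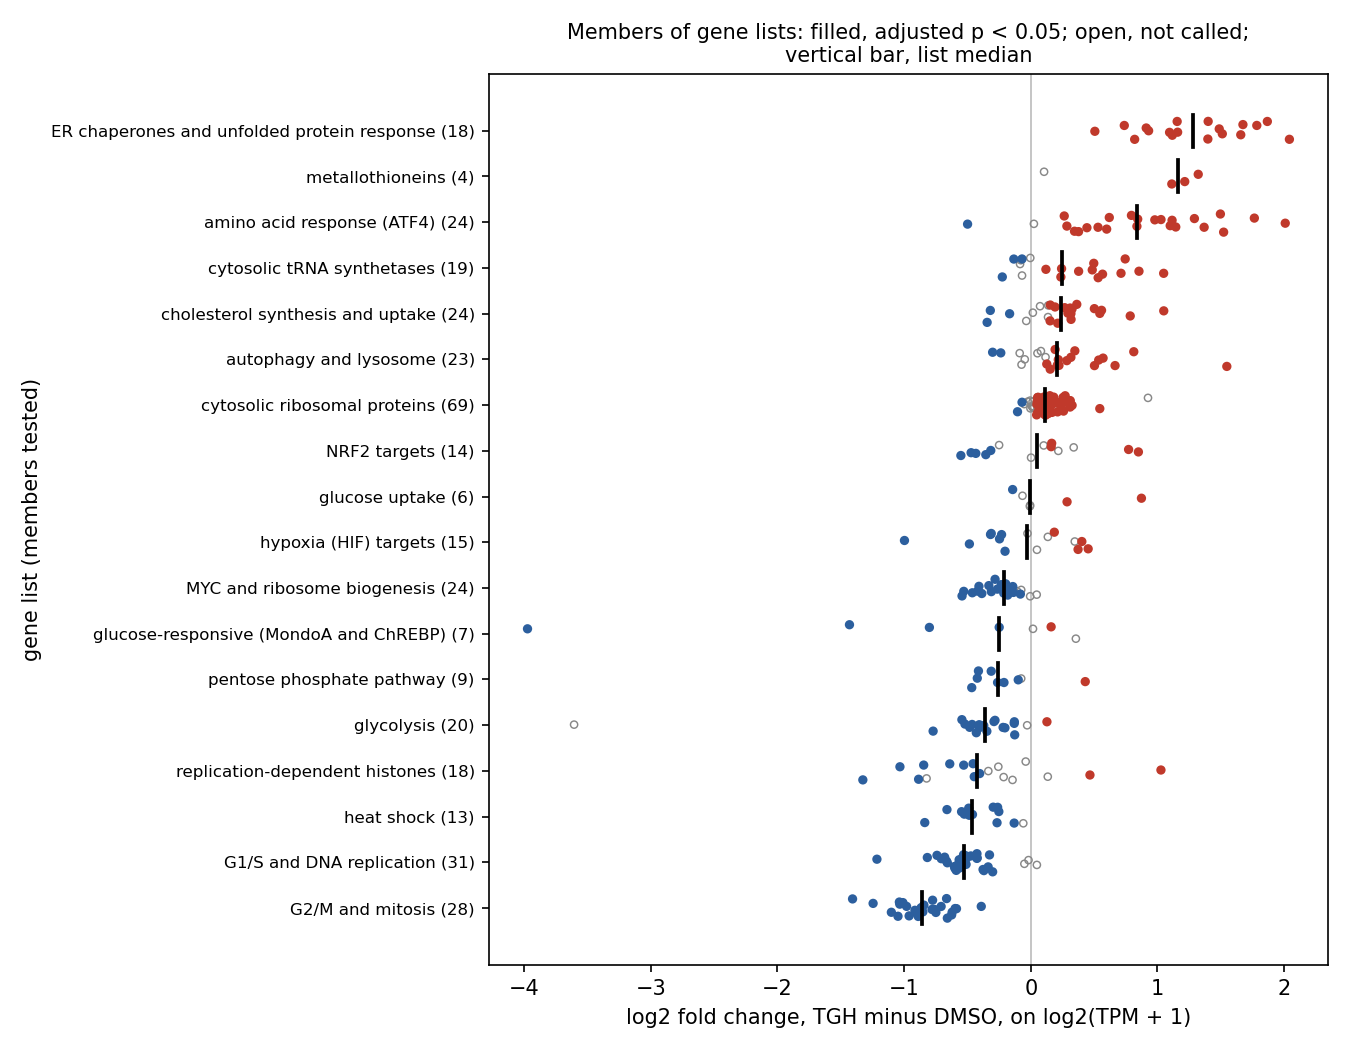
Log2 fold change (TGH minus DMSO, on log2(TPM + 1)) of the members of 14 called lists and of the glucose uptake, glucose-responsive, hypoxia and NRF2 lists, with the number tested beside each name. Filled points passed the test in the higher (red) or lower (blue) direction, open points did not, and the vertical bar is the list median, 1.28 for ER chaperones and -0.86 for mitosis genes. The open point of the glycolysis list near -3.60 is PKM.

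Cytosolic tRNA synthetases, which charge tRNAs with amino acids, had 12 higher and 3 lower of 19 (12 and 5 adjusted over the list alone). AARS rose by 1.05, SARS by 0.74, GARS by 0.71 and EPRS by 0.53 (camera adjusted p = 0.0073, and adjusted p = 0.325 with an estimated correlation). For glutamine and amino acid transport 9 of 15 were higher and 3 lower, the same adjusted over the list alone, with SLC1A4 up by 0.94 and SLC1A5 by 0.41 (camera adjusted p = 0.108, but 0.0476 under quantile normalization). Autophagy and lysosome genes had 15 higher and 2 lower of 23, the same adjusted over the list alone. WIPI1, which acts in autophagosome formation, rose by 1.55, NEU1, a lysosomal sialidase, by 0.81 and MCOLN1, a lysosomal channel, by 0.54 (camera adjusted p = 0.0055, and adjusted p = 0.115 with an estimated correlation). Cholesterol synthesis and uptake genes had 16 higher and 3 lower of 24, the same adjusted over the list alone, with STARD4, a sterol carrier, up by 1.05 and MVD by 0.56 (camera adjusted p = 0.0039, and adjusted p = 0.143 with an estimated correlation). In fatty acid synthesis 2 were higher and 5 lower of 12 (2 and 6 adjusted over the list alone), among them SREBF1 at -0.47 and ACLY at -0.29 (camera adjusted p = 0.160).

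Cell division transcripts fell. All 28 genes of G2/M and mitosis were lower, also adjusted over the list alone, with a median of -0.86 (camera adjusted p = 2.2e-18, and adjusted p = 0.0241 with an estimated correlation). PLK1 fell by 1.24, MKI67, the marker of cycling cells, by 1.10, CCNA2, cyclin A, by 1.04 and TOP2A, a topoisomerase, by 0.98. Of 31 genes of G1/S and DNA replication 28 were lower and 3 were not called, the same adjusted over the list alone, with a median of -0.53 (camera adjusted p = 3.2e-13, and adjusted p = 0.0241 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, fell by 1.21 and MCM7, part of the replicative helicase, by 0.82. Replication-dependent histones had 9 lower and 2 higher of 18, the same adjusted over the list alone, with HIST2H2AC at -1.03 and HIST1H1C at -0.53 (camera adjusted p = 0.0134, and adjusted p = 0.181 with an estimated correlation). Histone genes are near-identical to each other, so their reads may be split between copies.

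Cyclin D and CDK inhibitors went both ways, with 3 higher and 4 lower of 11, the same adjusted over the list alone (camera adjusted p = 0.578). The list's median was -0.03 and its test pointed down, while its mean was 0.01. CDKN1A, the inhibitor p21, rose by 0.95, while CCND1, cyclin D1, fell by 0.40 and CDKN2C, another inhibitor, by 0.59. The p53 target list, which includes CDKN1A and shares 5 members with other lists, had 7 higher and 1 lower of 16, the same adjusted over the list alone, with TP53I3 up by 0.72 (camera adjusted p = 0.160). PC-3 is known to lack functional p53. The apoptosis list, also with 5 shared members, had 5 higher and 5 lower of 17, the same adjusted over the list alone (camera adjusted p = 0.759).

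Heat shock genes, most of them chaperones outside the ER, fell. Of 13 measured 12 were lower and 1 was not called, the same adjusted over the list alone, with a median of -0.46 (camera adjusted p = 5.6e-07, and adjusted p = 0.0276 with an estimated correlation). HSP90AA1, an inducible HSP90 of the cytosol, fell by 0.84, HSP90AB1 by 0.66, HSPA8, a constitutive HSP70, by 0.55 and HSPD1, the mitochondrial chaperonin, by 0.53. Genes of MYC and ribosome biogenesis had 20 lower and 4 uncalled of 24 (22 lower adjusted over the list alone), with a median of -0.21 (camera adjusted p = 1.1e-07, and adjusted p = 0.0241 with an estimated correlation). DKC1 fell by 0.54, NOLC1 by 0.53, NPM1 by 0.46 and NCL by 0.42, all proteins of the nucleolus. Cytosolic ribosomal proteins had 51 higher and 2 lower of 69 (54 and 3 adjusted over the list alone), with a median of only 0.11 and RPL37A up by 0.33 (camera adjusted p = 1.3e-09, and adjusted p = 0.162 with an estimated correlation). Under quantile normalization 28 of them were higher and 8 lower. Metallothioneins, which bind metals, had 3 higher of 4 (4 adjusted over the list alone), with MT1X up by 1.32, MT1M by 1.22 and MT1F by 1.11, and MT2A at 0.10 (adjusted p = 0.0526) not called (camera adjusted p = 0.020, and adjusted p = 0.162 with an estimated correlation). MT2A was called under 5 other settings, with an adjusted p from 0.0171 to 0.0474, and these closely related genes may share reads.

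Several other lists had called members in both directions without a shift of the list. Of all genes kept 55.2% were called, so such calls are common and are no result about a list. In the TCA cycle 6 were higher and 7 lower of 22 (camera adjusted p = 0.515), with PC, pyruvate carboxylase, up by 0.88 and CS, citrate synthase, down at -0.51. Of 38 nuclear-encoded respiratory chain genes 16 were higher and 8 lower (0.433), with NDUFV1 at 0.26 and ATP5A1 at -0.23. Both lists had the same counts adjusted over the list alone. In the hypoxia list 4 were higher and 7 lower of 15 (0.860), the same adjusted over the list alone, with VEGFA at 0.40 and BNIP3 at -0.48. The NRF2 list had 4 higher and 5 lower of 14 (5 and 5 adjusted over the list alone; 0.860), with FTL, ferritin light chain, at 0.85 and GCLM, for glutathione synthesis, at -0.55. Its median of 0.05 and mean of 0.02 differ in sign from the test's direction.

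Among the other lists, the camera adjusted p was 0.513 for fatty acid oxidation (5 higher and 4 lower of 16), 0.860 for FOXO targets and insulin signalling (2 and 3 of 13), 0.508 for aryl hydrocarbon receptor targets (1 and 1 of 5), 0.468 for the interferon response (1 and 5 of 18), 0.877 for NF-kB and cytokines (5 and 5 of 15), 0.713 for YAP targets (4 and 5 of 10) and 0.860 for immediate-early genes (2 and 1 of 10). Adjusted over the list alone the counts were the same except for FOXO targets, with 1 higher, and aryl hydrocarbon receptor targets, with 0 higher. OAS3, an antiviral enzyme, fell by 0.60, IL8, a chemokine, by 0.64 and CTGF, a matrix protein, by 0.74, while TNFAIP3, an inhibitor of NF-kB signalling, rose by 0.64 and ANKRD1, a YAP target, by 0.44. The medians of the FOXO list (0.04) and of the immediate-early genes (-0.01) differ in sign from their tests.

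Markers of prostate and other cell types were also measured, and the examples named from the luminal, fibroblast, immune and structural RNA lists were chosen after their values were seen. The luminal prostate and androgen receptor list had 4 lower and 1 higher of 6 (camera adjusted p = 0.0701), with STEAP4 at -0.62 and HOXB13, a prostate transcription factor, at -0.55. The epithelial list had 7 lower and 1 higher of 12 (camera adjusted p = 0.0589, and adjusted p = 0.209 with an estimated correlation), with KRT8 at -0.51 and KRT18 at -0.45. Its adjusted p was 0.0483 after rescaling without small RNAs and 0.0323 against DMSO replicate 3 alone, where no control spread enters. The mesenchymal list had 5 higher and 2 lower of 11 (0.336), with THBS1, thrombospondin, at -0.69. These 3 lists had the same counts adjusted over the list alone. The basal list had 2 members kept, both uncalled, while neuroendocrine and endothelial markers had 0 kept. Of fibroblast markers COL1A1 alone was kept, at -0.23, a call lost without TGH replicate 1 (adjusted p = 0.0546). Of 2 immune markers kept CD68, a lysosomal protein, rose by 1.12 and the other was not called, but both passed adjusted over the list alone. The structural RNA list had 2 higher and 1 lower of 4, the same adjusted over the list alone, with MALAT1 at 0.38, NEAT1 at 0.24 and RPPH1 at -0.89 (camera adjusted p = 0.795, median -0.11 against an upward test). Mitochondrially encoded genes were not analysed here.

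Of 36 lists tested 14 were called, 7 higher and 7 lower. With an estimated correlation 7 of them were also called, and on ranks 14 lists were called. The 14 called lists had the same call and direction under median scaling, quantile normalization and rescaling without small RNAs.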

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

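Of the settings here, DMSO replicate 3 as the only control and exact zeros taken as missing were chosen after the data had been seen. Across 130 named genes 2321 values were recomputed: 2293 stayed on the same side of the threshold with the same sign, 19 were no longer called, 9 became called, and 0 changed sign. Many of these genes were named for a large change or a small p in these same data, which favours calls that stay. Settings that alter only the variances cannot change a sign. The genes that changed in this tally were SNORA84, SNORA34, BCYRN1, SLC2A1, ARRDC3, COL1A1, MT2A and PKM. The tally did not hold every gene under the naming rule, nor APLP2, CNBP, CUX1, GPN1 and SUPT7L, named below for their zeros. With zeros as missing APLP2, CNBP and CUX1 became called. CNBP (2.05 to -0.10), CUX1 (-1.28 to 0.38), GPN1 (-1.85 to 0.03) and SUPT7L (-1.13 to 0.06) changed sign. Genes at least 2-fold higher numbered 113, but 249 at a pseudocount of 0.1 and 44 at 5. Genes at least 2-fold lower numbered 31, but 9 at a pseudocount of 5 and 19 at a mean of at least 5 TPM, where fewer genes were tested. With no filter on low values the glucose-responsive list became called (mean -0.661, adjusted p = 0.0454), and the cause was not tested. Its adjusted p over all alternatives lay between 0.0454 and 0.325. Against DMSO replicate 3 alone the means of 4 lists not called either way changed sign, to 0.000638 for the TCA cycle, 0.0229 for FOXO targets, 0.00188 for apoptosis and -0.0298 for immediate-early genes, and the cause was not tested. Leaving out 1 library gave 2858 to 3535 higher and 2557 to 3175 lower genes. Quantile normalization gave 2964 higher and 3643 lower genes, so 44.9% of calls were higher, and 3 genes were called the opposite way. The replicate block gave 3273 higher and 2958 lower genes and ended no call of the primary lists, and under it MT2A became called (adjusted p = 0.0359). Same-numbered libraries had residual correlations of 0.01, 0.05 and 0.23, and the other pairs across groups had -0.16 to 0.10. With so few libraries these values do not settle whether the numbers pair them. Rows sharing a symbol were not summed, since there were 0, and lists were not tested with zeros as missing, which camera cannot take. Depth per library is known only to about a factor of 2, so what it limits for low genes was not quantified.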

Other observations

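The ER chaperone and glucose-responsive lists and their camera tests were fixed beforehand. All other gene lists and tests in this part, and the use made of those lists here, were chosen only after the results had been seen. The same holds for the genes named here that the report does not name, so each pattern is a hypothesis. Camera p-values of the lists chosen afterwards were adjusted over those lists alone, not together with the fixed lists. They come from the same data that prompted the lists, so they are no independent support for any of these patterns. Beyond chaperones, other parts of the secretory route were higher with TGH. Of 9 oligosaccharyltransferase subunits, which add glycans to proteins in the ER, 8 were higher (STT3A by 0.39; limma camera adjusted p = 1.3e-05). ER-associated degradation genes were higher in 8 of 9, with SYVN1 up by 0.92 and DERL2 by 0.79 (5.0e-05). Of 21 translocon and signal peptidase genes 13 were higher and 1 lower, with SEC61A1 up by 0.37 (0.00046). With an estimated correlation the adjusted p of these lists was 0.0396. COPII coat genes had 7 higher and 2 lower of 10, with SEC24D up by 0.93 (0.0266, and adjusted p = 0.212 with an estimated correlation). The hexosamine pathway, which makes the sugar donor for glycans, had 5 higher and 1 lower of 8, with GFPT1, its first enzyme, up by 0.60 and PGM3 by 0.48 (0.0370, and adjusted p = 0.188 with an estimated correlation).

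Lower groups included condensin and cohesin, with 8 of 8 (SMC4 fell by 0.72 and NCAPG by 0.79; camera adjusted p = 3.7e-06, and adjusted p = 0.0396 with an estimated correlation). The proteasome had 25 lower and 0 higher of 31, with PSMD14 at -0.27 and a median of -0.21 (2.1e-09, and adjusted p = 0.0375 with an estimated correlation). All 8 subunits of the cytosolic chaperonin CCT were lower, with CCT5 at -0.44 (1.3e-05, and adjusted p = 0.0731 with an estimated correlation). Purine and pyrimidine synthesis had 9 lower of 13, with PAICS at -0.51 (0.0011, and adjusted p = 0.0396 with an estimated correlation). Tubulins had 5 lower of 9, with TUBB at -0.50 (0.0266, and adjusted p = 0.188 with an estimated correlation). The counts of calls per list come from the adjustment over all genes.

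ER chaperones rose while TXNIP and ARRDC4 fell. Low depth of DMSO replicates 1 and 2 is argued against, since the ER list's median was 1.20 against DMSO replicate 3 alone. A trend with GC content and transcript length is argued against as the whole cause. Over the genes matched, fold change hardly followed length (Spearman correlation -0.033) or GC content (0.060). The median of genes of like length and GC content was then taken off each gene, which moved 5001 genes by over 0.05. What share of that movement is trend and not scatter was not tested. After this step the median of the ER list was 1.16, with TXNIP at -3.95. Lower glucose-dependent transcription may account for the TXNIP and ARRDC4 part, which stays open. The glucose-responsive list was not called (camera adjusted p = 0.0795). That list holds TXNIP and ARRDC4 themselves, so its test is no separate evidence on why they fell. An effect of TGH, which the design names, also stays open for both parts. Lower glucose-dependent transcription could be a part of such an effect and is no rival to it. Whether glucose bears on the ER part was not tested.

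Small RNAs were among the largest rises, with 8 of 133 called higher. Called in either direction were 8.27% of the small RNAs, against 55.7% of the other genes. Low depth of DMSO replicates 1 and 2 may contribute to some of these rises: small RNAs at 0 numbered 72 and 76 in those libraries against 38 in DMSO replicate 3 and 41, 42 and 30 with TGH. For 4 of the 8 (MIR941-2, SNORA60, SNORA78 and RNU11) DMSO replicate 3 is at 0 too. Their rise of 3.97 to 4.66 is the same against that library, because it starts from 0 in every control. The zeros in DMSO replicate 3 argue against the shallow controls alone as the source. This rests on 1 library, whose depth relative to the others is known only to about a factor of 2. The other 4 went from 3.41 to 4.52 (MIR3652), 4.03 to 2.25 (SNORA84), 1.12 to 1.03 (SNORA76) and 1.01 to 0.25 (SCARNA9) against DMSO replicate 3 alone, a median ratio of 0.738 after that test had been changed from the median of all 8, which could not move, so depth stays open for these. Counting noise of short RNAs may contribute too. For each called rise the SD within groups was divided by that of other genes at the same level, and the median ratio was 5.21. This median need not hold for each row, and the 4 rows at 0 in every control had no spread in DMSO. The ratio was first taken over all 133 small RNAs (23.2) and narrowed to the called ones after that value had been seen. A response to TGH also stays open.

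Expressed coding genes were listed at exactly 0 in 1 library (APLP2, CNBP, CUX1, GPN1, PKM, SLC4A1AP and SUPT7L) or in 2 (CHD3, in DMSO replicate 3 and TGH replicate 3), 8 genes with 9 zeros. Of these, 3 (GPN1, SLC4A1AP and SUPT7L) are neighbours in the RefSeq annotation of GRCh38.p14 and are at 0 in the same library, TGH replicate 2, a count that random genes seldom gave (permutation p = 0.0003, 10000 draws). That the estimate failed for a locus in that library may be the source for these 3, while the other genes have no such neighbour. Of those, PKM and CUX1 are also at 0 in TGH replicate 2, APLP2 in DMSO replicate 3 and CNBP in DMSO replicate 2. Low depth of DMSO replicates 1 and 2 is argued against, because only 1 of the 9 zeros lies in those libraries. No biological explanation was tested.

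The number of genes called between TGH and DMSO was 6635, and the highest of the other splits of the 6 libraries into 3 and 3 called 1. Each other split has TGH and DMSO libraries in both groups. A difference between TGH and DMSO then enters the spread, so few calls were to be had there and no conclusion is drawn from the contrast. The 10 splits, of which 1 gave as many calls (the real one), are too few for a share under 0.05.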
